A study of Glycine max with 8 samples.

How the data were processed

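Genomic DNA of root hairs and of stripped roots came from seedlings of the soybean cultivar Williams 82 that had germinated for 3 days and were then kept for 3 h at 25 °C or 40 °C, per the labels' protocols. There were 8 libraries in 4 groups of 2, grouped by the cell type and temperature in their titles. Per the labels' protocols, the DNA was mixed with unmethylated lambda DNA, sheared, ligated to adapters, treated with bisulfite and amplified by PCR. The lambda reads are not part of the deposited files and were not used here, so the share of cytosines left unconverted is unknown. The deposited files hold, for each library, a count of methylated reads and a count of all reads at each listed cytosine with its strand and context, per the file headers. The header gives the column of all reads only as h, and it is read as the total because no methylated count exceeded it. The aligner, the caller, the genome build and the filters are not given in the sources used here. The files list only cytosines called as methylated, and the call depended on depth: CHH sites with 2 methylated reads were listed up to a depth that differed between libraries, and a further methylated read was needed from 16, 18, 19, 21, 22, 26 or 31 reads on.

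No genome of this species was used, and the gene table at hand (assembly Glycine_max_v4.0) did not match the build of the files, since listed positions on chromosome 18 reached 62.3 Mb while its last gene there ended at 58.3 Mb. Gene bodies, regions upstream of genes and the planned gene lists were therefore not analysed here, and windows of 2 kb took the place of genes. No coordinate was converted, and positions are those of the files. The sequence around a site could not be read, so CHG sites were split into CCG and CWG, with C or else A or T as the middle base, by their listed neighbours, and CHH sites were not split. Gene density was replaced by CHG-site density for the division of chromosomes.

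A methylation level was the sum of methylated reads over the sum of all reads at sites listed in all 8 libraries with at least 4 reads in each, per library, as a percentage. This choice compares the same sites in every library, at the price of leaving out sites that a library does not list, most of all in CHH. Numbers of listed sites were taken as deposited, and, because the call depends on depth, again at matched depth, meaning sites with 6 to 10 reads and at least 2 methylated reads in that library. The matched-depth number was expressed per listed CG site. Window classes came from sites listed in any library: of windows with at least 10 CG sites, CG-only windows had a ratio of CHG to CG sites under 0.2 and multi-context windows a ratio of at least 0.5, with intermediate windows between, and a further class had at most 2 CG and CHG sites. Bins of 500 kb were divided into 3 equal parts at 19.2 and 55.2 CHG sites per 2 kb window.

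Single values were compared with two-sided exact permutation tests. For 4 libraries against 4 there are 70 arrangements and the smallest p is 0.0286; permuting within a cell type or temperature gives 36 arrangements and a smallest p of 0.0556. The difference between cell types in the change with temperature of a single value was tested in a linear model of the 4 groups. The model has 4 residual degrees of freedom and assumes an equal spread in the groups. Temperatures were also exchanged within cell types. That exchange assumes no change with temperature in either cell type, so a change common to both raises its p. It therefore does not test the difference alone. Benjamini-Hochberg adjustment was made over each family of measures. Nothing in the labels says that replicates came from separate seedling batches, so all p-values measure only the spread between libraries. Windows with at least 5 sites were tested with a quasi-binomial logistic model of methylated and all reads, fitted to the 4 groups, with the Pearson dispersion moderated by limma's squeezeVar function, a two-sided quasi-F test and Benjamini-Hochberg adjustment over the windows of a context. A window was called at an adjusted p under 0.05. The median number of reads per window and library was 98 in CG, 110 in CHG and 72 in CHH. The pooled comparisons of cell types and of temperatures used the same model with 2 groups of 4. The number of listed CHH sites per window was tested with edgeR's quasi-likelihood test, with each library's total of such sites as its size. The CHH share of listed CHH and CG sites was tested with the quasi-binomial model, in windows with at least 10 such sites in each library. Windows of 100 kb needed at least 50 sites. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and edgeR 4.0.16.

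The window test was tested on simulated data for the comparison at 25 °C. Depths were real, and each window's level was pooled over all 8 libraries. Changed windows were lowered in root hairs at 25 °C, so the recovery of rises was not simulated. Each window was given the median dispersion of its context (1.21 in CG, 1.11 in CHG and 1.38 in CHH). Windows with a larger spread and the rule for listing sites were not simulated, so the rates below hold for these settings only. With no change it made 0 false calls in each context, and with 200 windows changed by 20 points 6 of 97 calls were false in CG, 9 of 118 in CHG and 4 of 84 in CHH. Of 200 windows changed by 20 points it recovered 45.5% in CG, 54.5% in CHG and 40.0% in CHH, and of 200 changed by 10 points it recovered 6.50%, 1.50% and 0%. The edgeR test of site numbers recovered 79.0% of 200 windows changed 2-fold among 15866 windows. Its simulated counts had the same assumed spread in all windows, and the changed windows were taken from those with larger counts.

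The alternatives fixed before the data were examined were a minimum of 10 reads, every listed site with at least 4 reads whichever libraries list it, edgeR's test, the replicate number as a block, the other factor as a covariate, equal weight for each site, site numbers at 8 to 15 or at least 10 reads, TMM factors and leaving out each library in turn. The matched-depth setting, the CHH share of windows, the 100 kb windows and the classes of windows by level were added after the data had been seen. Named windows follow a rule fixed before the data were examined: for each pairwise comparison and context, the 4 called windows with the largest rise and the 4 with the largest fall among those with at least 10 sites and no overlap between the libraries of both groups. Windows outside the rule are named as chosen after their values were seen.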

Results

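DNA methylation was measured by whole-genome bisulfite sequencing in root hairs, the tubular outgrowths of single epidermal cells, and in the stripped roots that remained after the hairs had been removed. The plants were soybean seedlings of the cultivar Williams 82, germinated for 3 days and then kept for 3 h at 25 °C or at 40 °C. The 8 libraries formed 4 groups of 2 replicates: root hairs at 25 °C, stripped roots at 25 °C, root hairs at 40 °C and stripped roots at 40 °C. Plants methylate cytosines in CG, CHG and CHH sequence, where H is A, C or T, and each context is maintained by its own enzymes. The design poses 3 questions: how a single cell type differs from the rest of the root, how heat changes methylation in each, and whether the heat response differs between them.

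Each library listed the cytosines called as methylated, with the methylated reads and all reads at each. Between 35.9 and 43.5 M (mega) cytosines were listed per library. Reads at listed sites summed to 236 and 254 M in the root hair libraries at 25 °C and to 261 and 257 M in stripped roots at 25 °C. At 40 °C they summed to 268 and 152 M in root hairs and to 309 and 328 M in stripped roots. A listed CG site had 4.86 and 4.97 reads on average in root hairs at 25 °C, 5.76 and 5.63 in stripped roots at 25 °C, 5.32 and 3.75 in root hairs at 40 °C, and 6.40 and 6.72 in stripped roots at 40 °C. Root hair libraries were thus the shallower ones. Of the 18.3 M CG sites listed in any library, 53.9% were listed in all 8. For CHG sites this share was 44.1% of 18.1 M, and for CHH sites it was 2.14% of 36.9 M. Methylation levels below are methylated reads as a percentage of all reads at sites listed in all 8 libraries with at least 4 reads in each, and they describe such sites, not the whole genome. These were 2868984 CG, 2551284 CHG and 559805 CHH sites. Counting error covers reads alone, and reads without molecular identifiers are not independent molecules.

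At sites listed in all 8 libraries, root hairs had higher methylation levels than stripped roots in all 3 contexts. The CG level was 84.1% ± 0.906 in root hairs and 80.8% ± 1.03 in stripped roots (SD, n = 4 libraries each). The CHG level was 76.8% ± 0.900 against 71.8% ± 0.935, and the CHH level was 53.9% ± 2.34 against 37.4% ± 0.930. The differences were 3.23, 5.01 and 16.5 percentage points, and every root hair library lay above every stripped root library in each context. They were of similar size at 25 °C (3.18, 4.93 and 15.9 points) and at 40 °C (3.28, 5.08 and 17.0 points). The same direction held on 20 of 20 chromosomes for each context. The exact permutation test gave a two-sided p of 0.0286 for each difference, the smallest that 70 arrangements allow, and 0.0571 after adjustment over the 6 level comparisons. At sites with 6 to 10 reads and at least 2 methylated reads, the differences were 2.48, 4.17 and 5.44 points. This setting was chosen after the data were seen, to match depth. The CHH difference was thus less than the 16.5 points at sites listed in all libraries. Listing a CHH site of 6 to 10 reads took at least 2 methylated reads. The lowest level a listed site can have is thus higher where reads are fewer. Root hair libraries were the shallower ones, so listing can raise their CHH level. The 16.5 points therefore do not measure the cell types alone.

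**Figure D1:**
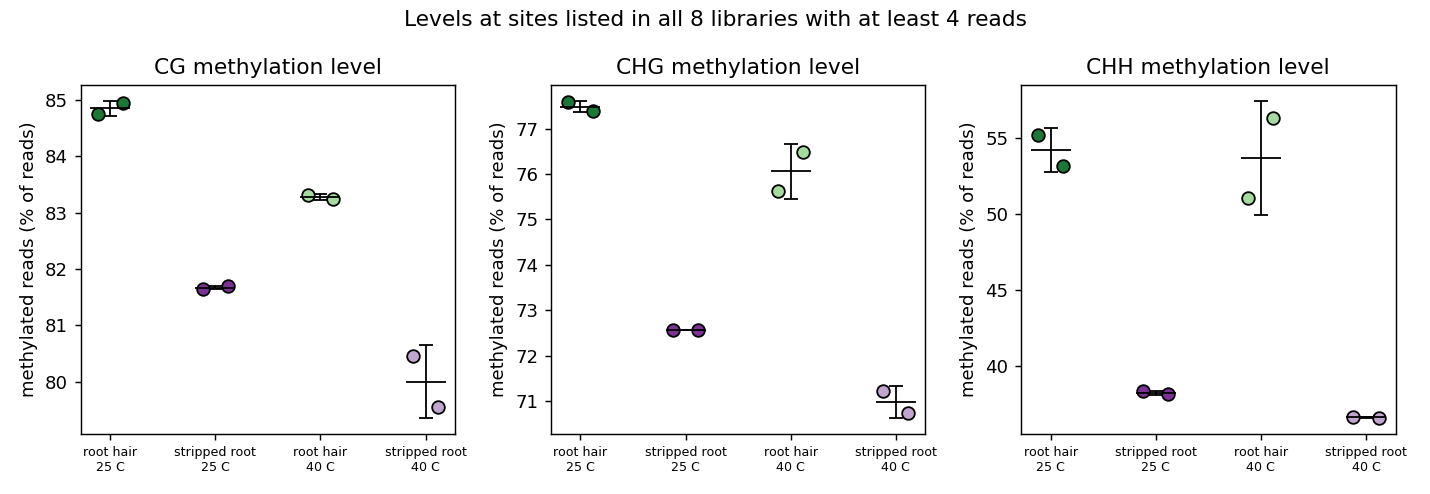
Methylation level (percent of reads methylated, vertical axis) at sites listed in all 8 libraries with at least 4 reads, by group and context. Points are libraries, bars the group mean and SD (n = 2), and the vertical axes do not start at 0. The 4 root hair libraries lie above the 4 stripped root libraries in each panel, with means of 54.2% and 38.2% for CHH at 25 °C.

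Root hairs also had more listed CHH sites per CG site at matched depth. A higher level at the same cytosines can list more of them, so this measure is not separate from the level. Among sites with 6 to 10 reads, 1.71 ± 0.139 CHH sites were listed per CG site in root hairs and 1.08 ± 0.0404 in stripped roots (SD, n = 4 libraries each), which was 58.1% more. The difference was 0.712 at 25 °C and 0.546 at 40 °C. At each read depth from 6 to 10, the 5 depths taken singly, no stripped root library reached the lowest root hair library. Root hairs had the higher value in 1907 of 1907 bins of 500 kb and on 20 of 20 chromosomes, and in 1708 bins all 4 root hair libraries lay above all 4 stripped root libraries. CHG sites per CG site differed far less, at 1.01 against 0.989 (exact permutation p = 0.143). The exact permutation p for the CHH difference was 0.0286, or 0.0714 after adjustment over the 10 comparisons at matched depth. This measure was chosen after the plain numbers of listed sites were seen. Those were 13.2 ± 2.60 M CHH sites in root hairs and 11.4 ± 0.993 M in stripped roots (SD, n = 4 each; exact permutation p = 0.229), a difference that turned to -2.77 M when sites needed 10 reads.

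**Figure D2:**
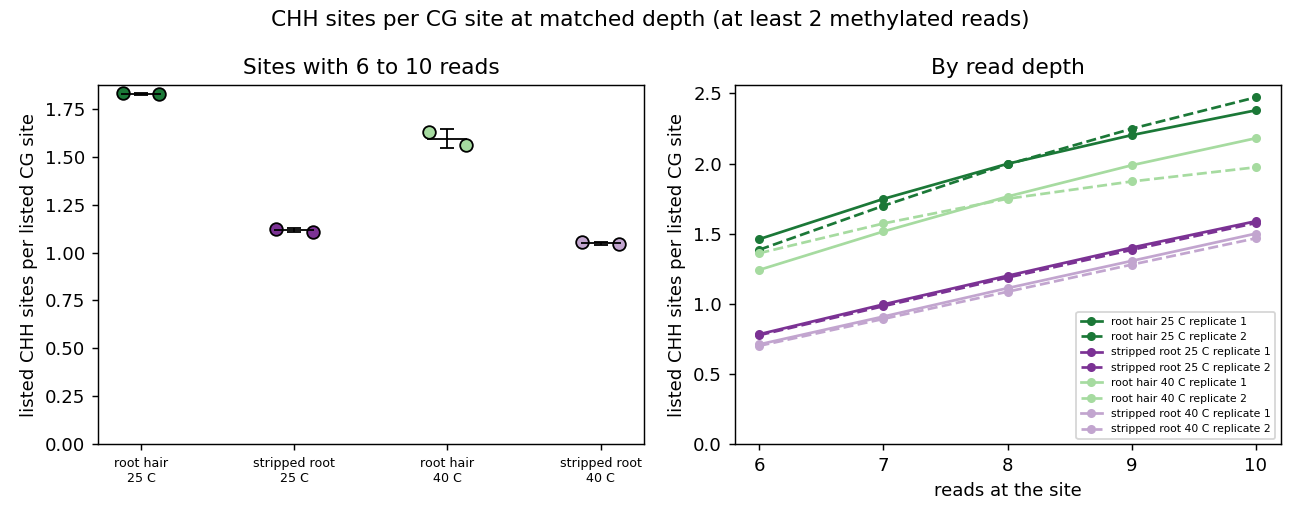
Listed CHH sites per listed CG site at sites with at least 2 methylated reads. The left panel shows each library as a point with the group mean and SD (n = 2) for sites with 6 to 10 reads, and the right panel shows each library at each read depth. Root hair libraries at 25 °C have a mean of 1.83 and stripped root libraries at 25 °C a mean of 1.12, and the cell types do not overlap at any of the 5 depths.

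Within windows of 2 kb, the share of CHH among listed CHH and CG sites of matched depth was higher in root hairs in 86.3% of 171329 windows, by a median of 7.53 percentage points. The quasi-binomial test with temperatures pooled called 22163 windows, of which 22066 were higher and 97 lower in root hairs. The same test called 0 windows at 25 °C alone and 0 at 40 °C alone, with 43315 and 32919 windows at an unadjusted p under 0.05; edgeR was not run on this share. It was higher in root hairs in 84.8% of windows at 25 °C and in 76.1% at 40 °C. The pooled count was 5051 and 6260 without root hair replicate 1 or 2 at 25 °C, 10665 and 9680 without stripped root replicate 1 or 2 at 25 °C, 11551 without root hair replicate 1 at 40 °C, and 8187 and 8864 without stripped root replicate 1 or 2 at 40 °C. Counting listed CHH sites per window without regard to depth, edgeR called 6000 of 317305 windows, 3726 higher and 2274 lower in root hairs. With sites of at least 10 reads it called 4494 higher and 5905 lower. The test sets each window against the library's total of such sites. These calls thus compare how the sites are spread over windows, not the plain site number. Without any 1 library the count for all listed sites was 2309 to 3771.

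The excess of methylation level in root hairs was unevenly spread along chromosomes. CHG methylation marks transposon-rich heterochromatin in plants, so the 500 kb bins were sorted into 3 equal parts by their density of CHG sites. The CG difference was 3.95 points in the CHG-dense part and 1.46 points in the CHG-sparse part, where the exact permutation p was 0.143. The gap between these parts was itself 2.49 points wider in root hairs (exact permutation p = 0.0286, adjusted 0.0571). CHH sites per CG site were 74.7% more numerous in root hairs in the CHG-dense part and 35.5% in the CHG-sparse part. These ratios rest on a base that was higher in the CHG-sparse part. As a plain difference, the excess of CHH sites per CG site was of similar size in both parts. The difference in CHH level went the other way from that in CG level, with 14.0 points in the CHG-dense part and 20.2 in the CHG-sparse part. Read depth was lower in root hairs in each part, by -23.2% in the CHG-dense and -25.0% in the CHG-sparse part.

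**Figure D3:**
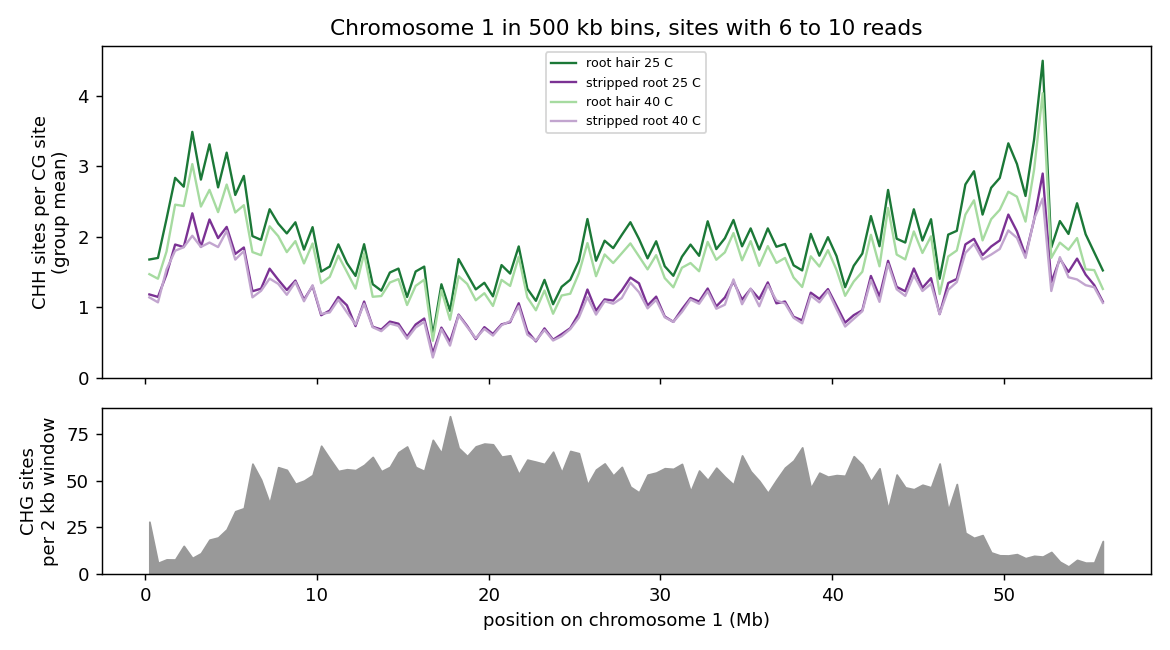
Chromosome 1 in bins of 500 kb, with position in Mb on the horizontal axis. The upper panel shows CHH sites per CG site at sites with 6 to 10 reads as the mean of each group's 2 libraries, without error bars, and the lower panel shows CHG sites per 2 kb window in any library. The root hair lines run above the stripped root lines of the same temperature, with a highest value of 4.50 in root hairs at 25 °C and 2.90 in stripped roots at 25 °C, and on the whole genome the root hair value averages 2.24 in the CHG-sparse and 1.34 in the CHG-dense part.

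Windows methylated in CG alone, a pattern that in plants is typical of the bodies of expressed genes, stood apart from windows methylated in several contexts. In the 40010 CG-only windows the CG level was 80.0% ± 0.900 in root hairs and 79.1% ± 1.10 in stripped roots (SD, n = 4 libraries each), a difference of 0.854 points (exact permutation p = 0.286). In the 263834 multi-context windows it was 85.2% ± 0.921 against 81.4% ± 1.04, a difference of 3.75 points (exact permutation p = 0.0286). The difference between these classes was 2.90 points larger in root hairs (exact permutation p = 0.0286, adjusted 0.0762 over the family). Within CHG, sites with C as the middle base (CCG) had 57.8% ± 1.05 in root hairs and 55.8% ± 0.817 in stripped roots, and those with A or T there (CWG) had 78.1% ± 0.910 and 72.9% ± 0.95. The CWG difference of 5.21 points exceeded the CCG difference of 2.02 points by 3.19 points (exact permutation p = 0.0286, adjusted 0.0571). The strands of a CG pair differed by 14.3 points on average in root hairs and by 15.8 in stripped roots (exact permutation p = 0.0286). Counting error at each site adds to this difference between strands. That error is smaller where a larger share of reads is methylated, and root hairs had the higher CG level. The values thus cannot show that the strands were more alike in root hairs.

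At 25 °C, root hairs and stripped roots differed in many 2 kb windows, nearly always with more methylation in root hairs. Of 193733 windows tested for CG, 5213 were higher and 259 lower in root hairs. For CHG, 11721 of 152094 were higher and 112 lower, and for CHH 13520 of 37230 were higher and 2 lower. The CHH levels can carry the effect of listing and depth described above. At matched depth 99.2% of the 11678 CHH windows called higher that could be tested kept the direction. The same 25 °C libraries made the calls, so much of this agreement is built in. It does not separate the calls from listing and depth. At 40 °C, 97.4% of all CHH windows tested had this direction, called or not. The median difference was 13.4 points in CG windows called higher and -16.8 points in those called lower. CG windows that were higher lay mostly in multi-context windows (88.4% of calls, 77.8% of windows tested) and those that were lower lay in CG-only windows more often than the windows tested (27.0% against 13.1%; Fisher's exact adjusted p = 6.58e-09 over 140 tests, with neighbouring windows not independent). CHH calls gathered in the CHG-sparse part of the chromosomes, which held 52.8% of them and 38.1% of the windows tested.

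Single windows at 25 °C showed large differences, in both directions for CG and CHG. Of the 51 windows named for the pairwise comparisons and the interaction, 12 kept their call under all settings run. At matched depth 7 of the 35 that could be tested kept it. The largest CG rise was in the window on chromosome 10 from 21598001 to 21600000, with 78.5% ± 6.82 in root hairs and 43.3% ± 6.15 in stripped roots (SD, n = 2 each; limma-moderated adjusted p = 0.000445), followed by windows on chromosome 20 at 24502001 (35.1 points), chromosome 9 at 15850001 (32.9 points) and chromosome 9 at 26058001 (32.1 points). The largest CG fall was in a CG-only window on chromosome 14 from 42690001 to 42692000, at 52.6% ± 2.92 in root hairs and 88.5% ± 4.64 in stripped roots (SD, n = 2 each; limma-moderated adjusted p = 0.000219). It had 64 to 138 reads per library. Further CG falls were on chromosome 13 at 24854001 (-27.4 points), chromosome 20 at 36328001 (-25.9 points) and chromosome 15 at 1630001 (-23.0 points). At 40 °C the rise on chromosome 9 at 26058001 was small (72.9% in root hairs against 70.9% in stripped roots). The other named CG rises and falls kept their direction at 40 °C. The window on chromosome 20 belonged to the longest run of lower CG windows, 3 windows from 36328001 to 36334000 with a mean difference of -31.6 points, a region chosen after its values were seen. In CHG, the largest rise was on chromosome 6 at 41886001, with 92.5% ± 7.11 against 59.9% ± 3.22, and the largest fall on chromosome 4 at 39200001, with 59.6% ± 2.26 against 81.9% ± 0.227 (SD, n = 2 each). Other CHG rises were on chromosome 3 at 32826001 (28.1 points) and on chromosome 4 at 16206001 (27.2 points) and 32250001 (26.9 points). Other falls were on chromosome 9 at 37582001 (-21.1 points), chromosome 3 at 45680001 (-20.7 points) and chromosome 1 at 31670001 (-20.3 points). At 40 °C the falls on chromosomes 4 and 9 were small (65.0% in root hairs against 67.1% in stripped roots, and 78.2% against 81.9%). Those on chromosomes 3 and 1 were turned (74.3% against 67.7%, and 66.1% against 59.8%). The rise at 32250001 was absent at 40 °C (69.6% against 70.9%), and the other named CHG rises kept their direction. In CHH, the window on chromosome 14 from 47126001 to 47128000 had 76.9% ± 3.55 in root hairs and 24.9% ± 6.17 in stripped roots (SD, n = 2 each). It was followed by chromosome 4 at 13600001 (49.3 points), chromosome 18 at 37688001 (49.0 points) and chromosome 14 at 48252001 (48.4 points). The 2 windows with lower CHH, named after their values were seen, were on chromosome 15 at 37422001 (-8.33 points) and 48418001 (-15.1 points), and neither was lower in root hairs at 40 °C.

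The test at 25 °C was a quasi-binomial model with dispersions moderated by limma, called at a Benjamini-Hochberg adjusted p under 0.05. The number of CG calls fell to 2386 with edgeR, 1280 at matched depth and 149 with a minimum of 10 reads. CHG calls fell to 6859 at matched depth and 96 with 10 reads, and CHH calls to 147 with 10 reads. With every listed site, CHG and CHH calls rose instead. Without root hair replicate 1 or 2 or stripped root replicate 1 or 2 at 25 °C, the CG calls were 917, 973, 1412 and 2114 and the CHG calls 3103, 3647, 4719 and 5839; the CHH calls were 7725 without that root hair replicate 1 and 8867 without that stripped root replicate 2, and without root hair replicate 2 at 40 °C the CG calls were 8767 and the CHH calls 23131.

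At 40 °C root hairs again had the higher level in nearly all calls, with 7514 CG windows higher and 509 lower in root hairs. For CHG 13486 windows were higher and 177 lower, and for CHH 14905 were higher and 4 lower. The median difference was 14.2 points in CG windows called higher and -16.3 points in those called lower. Windows with a lower CG level were again more often CG-only than the windows tested (23.8% against 13.1%; Fisher's exact adjusted p = 1.62e-10). The 40 °C libraries did not enter the 25 °C difference, but all 8 libraries set the spread and the sites of both tests. The numbers given below for independent lists are thus only a guide. Of the 5213 CG windows higher at 25 °C, 95.7% had the same direction at 40 °C, against 70.5% of all windows tested, and 1389 were called at both, where 202 would be shared by independent lists. Of the 259 CG windows lower at 25 °C, 78.0% were lower at 40 °C, against 29.5% of all windows tested, and 30 were called at both, where 0.680 would be shared. The corresponding shares were 95.4% for higher CHG windows against 80.3% of all, 67.0% for lower CHG windows against 19.7%, and 99.4% for higher CHH windows against 97.4%, so nearly all CHH windows had this direction, called or not.

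Among single windows at 40 °C, the same CG-only window on chromosome 14 at 42690001 again showed the largest CG fall, with 53.7% ± 12 in root hairs and 86.4% ± 0.265 in stripped roots (SD, n = 2 each; limma-moderated adjusted p = 0.000629). Other CG falls were on chromosome 2 at 12106001 (-29.2 points), chromosome 11 at 14522001 (-28.9 points) and chromosome 13 at 22910001 (-28.7 points). At 25 °C the falls on chromosomes 2 and 11 were absent (92.1% in root hairs against 89.1% in stripped roots, and 87.5% against 88.2%). The fall on chromosome 13 was also seen at 25 °C (64.3% against 86.7%). The largest CG rise was on chromosome 19 from 50436001 to 50438000, with 85.3% ± 4.51 against 48.6% ± 2.45 (SD, n = 2 each; limma-moderated adjusted p = 9.56e-05). It was followed by chromosome 9 at 8968001 (34.3 points), chromosome 15 at 49946001 (33.2 points) and chromosome 1 at 28556001 (33.1 points). In CHG, the rises were on chromosome 5 at 22378001 (33.9 points), chromosome 20 at 29812001 (31.0 points) and 3526001 (30.6 points), and chromosome 11 at 17766001 (30.2 points). The CHG falls were on chromosome 1 at 4756001 (-25.9 points), chromosome 10 at 1050001 (-24.1 points) and 17160001 (-23.4 points), and chromosome 5 at 29744001 (-22.1 points). At 25 °C the fall at 17160001 was turned (64.7% in root hairs against 59.1% in stripped roots). The rise on chromosome 5 at 22378001 was small at 25 °C (79.7% against 76.5%). The other named CHG rises and falls had the same direction at 25 °C. In CHH, the window on chromosome 19 from 47712001 to 47714000 had 85.2% ± 8.79 in root hairs and 26.6% ± 4.58 in stripped roots (SD, n = 2 each). The next were on chromosome 18 at 55254001 (53.8 points), chromosome 20 at 11656001 (51.2 points) and chromosome 7 at 39182001 (51.2 points). A CHH fall of -10.3 points was on chromosome 6 at 46066001, over 37 sites (limma-moderated adjusted p = 0.0499). At 25 °C root hairs were higher there, at 78.2% against 61.6% in stripped roots, and with the replicate number as a block the call was lost. The other 3 windows with lower CHH, named after their values were seen, were on chromosome 9 at 8682001 (-31.0 points), chromosome 14 at 6550001 (-19.4 points) and chromosome 15 at 49950001 (-30.9 points). With every listed site the windows on chromosomes 9 and 14 turned to 4.87 and 9.61 points, so their direction rests on the choice of sites.

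The same test was used at 40 °C. CG calls fell to 3651 with edgeR, 652 at matched depth and 148 with a minimum of 10 reads. CHG calls fell to 4365 at matched depth and 89 with 10 reads, and CHH calls to 131 with 10 reads. With every listed site, CHG and CHH calls rose while CG calls fell. Without root hair replicate 1 or 2 or stripped root replicate 1 or 2 at 40 °C, the CG calls were 674, 3314, 4688 and 2063 and the CHG calls 2980, 5135, 8259 and 5127.

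**Figure D4:**
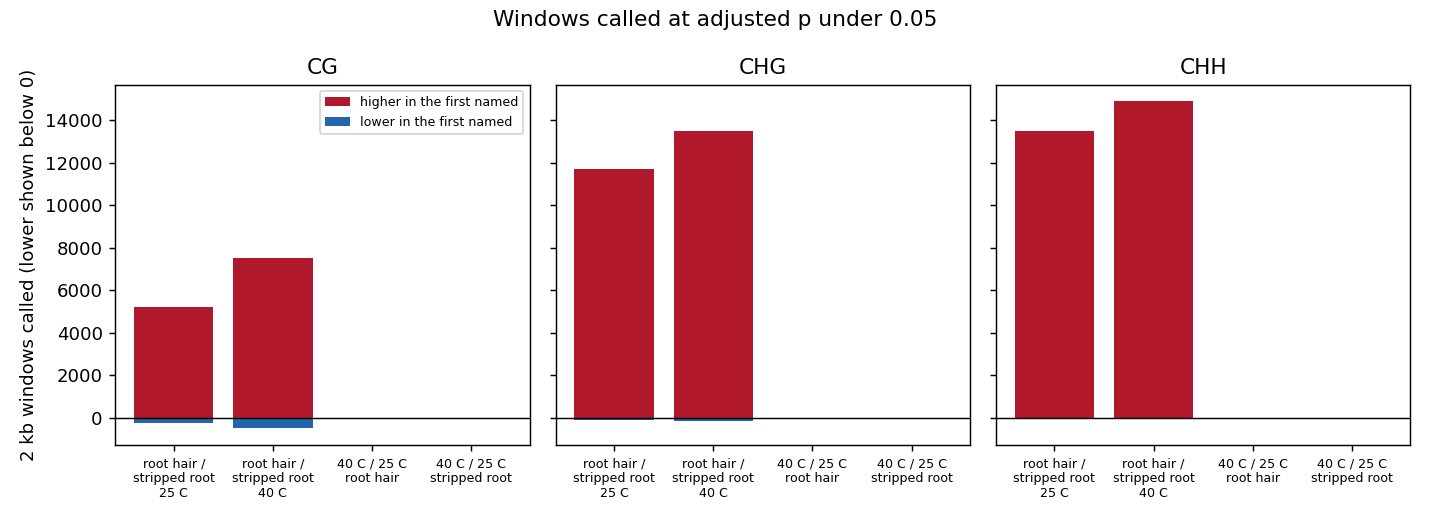
Number of 2 kb windows called at an adjusted p under 0.05 in each of the 4 pairwise comparisons, by context; windows lower in the group named first are drawn below 0. The bars start at 0, and the highest is 14905 CHH windows higher in root hairs at 40 °C. The bars for heat hold at most 2 windows and cannot be seen at this scale.

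With both temperatures pooled, 26568 CG windows were higher and 1399 lower in root hairs, 37932 CHG windows were higher and 374 lower, and 25171 CHH windows were higher and 3 lower. The 3 lower ones, named after their values were seen, were on chromosome 6 at 43824001 (-13.9 points), chromosome 9 at 8682001 (-22.5 points) and chromosome 11 at 9308001 (-7.86 points). CG and CHG calls fell in the same windows more often than independent lists would, with 9785 windows higher in both where 5892 would be shared. CHH calls did not go with them, as 2708 windows were higher in CG and CHH where 2975 would be shared, and 4495 in CHG and CHH where 4803 would be shared. Calls came in short runs, with the longest being 9 adjacent CG windows on chromosome 15 from 19618001 to 19636000, 10 CHG windows on chromosome 1 from 37472001 to 37492000 and 9 CHH windows on chromosome 9 from 28048001 to 28066000, all chosen after their values were seen. With a minimum of 10 reads the pooled counts were 319 for CG, 185 for CHG and 225 for CHH, and at matched depth they were 13879 for CG and 47180 for CHH. CG calls were 17898 and 18501 without root hair replicate 1 or 2 at 25 °C, and 17224 without stripped root replicate 2 at 40 °C. CHH calls were 38085 without root hair replicate 2 at 40 °C. The CHH counts of 47180 and 38085 exceed the 37230 windows of the main test. They come from larger sets of windows, so they do not by themselves show stronger differences.

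Heat for 3 h was accompanied by slightly lower levels in root hairs. The CG level was 84.8% ± 0.136 at 25 °C and 83.3% ± 0.0519 at 40 °C, the CHG level 77.5% ± 0.127 and 76.1% ± 0.607, and the CHH level 54.2% ± 1.45 and 53.7% ± 3.76 (SD, n = 2 each). CHH sites per CG site at matched depth were 1.83 ± 0.00536 at 25 °C and 1.60 ± 0.0509 at 40 °C. With 2 libraries against 2 no exact test can reach a p under 0.05. The linear model of the 4 groups was not applied to the change in 1 cell type, so these stand as values. No single 2 kb window was called with the main settings. Single windows were called with every listed site in CG and CHG, and with a minimum of 10 reads in CHG. The quasi-binomial test gave 0 windows in each context, with 13385, 9704 and 1821 windows at an unadjusted p under 0.05, and edgeR gave 0 in each, with 13739, 10104 and 1936. In a simulation of the comparison at 25 °C, the test recovered 6.50% of 200 CG windows changed by 10 points and 45.5% of those changed by 20 points, so differences of the size seen here were not detectable per window.

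Stripped roots also showed small decreases, of similar size to those in root hairs in CG and CHG level. The CG level was 81.7% ± 0.0323 at 25 °C and 80.0% ± 0.643 at 40 °C, the CHG level 72.6% ± 0.00398 and 71.0% ± 0.353, and the CHH level 38.2% ± 0.142 and 36.6% ± 0.0414 (SD, n = 2 each). CHH sites per CG site were 1.12 ± 0.0115 and 1.05 ± 0.00858. The quasi-binomial test called 1 CG window, 2 CHG windows and 0 CHH windows, with 13886, 10831 and 1821 at an unadjusted p under 0.05. With edgeR the calls were 0, 1 and 0, with 11055, 9362 and 1344 at an unadjusted p under 0.05. The CHG window on chromosome 1 from 18330001 to 18332000, with 25 sites, was at 84.2% ± 1.80 at 25 °C and 66.9% ± 6.01 at 40 °C (SD, n = 2 each; limma-moderated adjusted p = 0.0491). The others had fewer than 10 sites and are named after their values were seen. A CHG window on chromosome 11 at 31058001, with 7 sites, fell by 35.6 points (limma-moderated adjusted p = 3.7e-05), and a CG window on chromosome 1 at 30642001, with 6 sites, rose by 41.2 points (limma-moderated adjusted p = 0.0106). The CG call was lost with edgeR, which gave 0 calls. With every listed site the rise was 9.61 points and not called, while 2 other CG windows were called, both lower. It was also lost without stripped root replicate 2 at 25 °C (34.4 points), root hair replicate 2 at 40 °C (31.3 points) and stripped root replicate 1 or 2 at 40 °C (42.3 and 40.2 points). With a minimum of 10 reads no CG or CHG window was called for heat in stripped roots, and at matched depth no CHG window was called.

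With cell types pooled, the differences between 40 °C and 25 °C were -1.61 points in CG, -1.51 in CHG and -1.05 in CHH, and -0.152 in CHH sites per CG site. The exact permutation p was 0.286, 0.514, 0.686 and 0.514 without regard to cell type. When libraries were exchanged only within a cell type it was 0.0556 for CG, CHG and CHH sites per CG site, the smallest that 36 arrangements allow, and 0.389 for the CHH level. Without 1 library the cell types are no longer balanced, and the differences moved by over 1.5 times. They then ranged from -2.17 points (without root hair replicate 1 at 40 °C) to -0.911 (without stripped root replicate 2 at 40 °C) in CG and from -2.48 (without root hair replicate 2 at 40 °C) to -0.569 (without stripped root replicate 2 at 40 °C) in CHG. In CHH they ranged from -4.71 (without root hair replicate 2 at 40 °C) to 1.95 (without root hair replicate 1 at 25 °C), and the direction turned without either root hair library at 25 °C or either stripped root library at 40 °C. CHH sites per CG site ranged from -0.273 (without stripped root replicate 2 at 25 °C) to -0.0315 (without root hair replicate 1 at 25 °C). With all libraries, each difference had the same direction on 20 of 20 chromosomes, and CHH sites per CG site were higher at 40 °C in only 1 of 1907 bins and lower in the rest, in both cell types in 1594 of them. At matched depth the differences in level were -1.44, -1.17 and -0.247 points. In CG-only windows the CG level was 78.7% ± 0.721 at 40 °C and 80.4% ± 0.467 at 25 °C (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.0571), with no overlap between the temperatures. The decrease in CG was of similar size in multi-context windows (-1.64 points), in the CHG-dense part (-1.68 points) and in the CHG-sparse part (-1.52 points). The pooled quasi-binomial test called 0 windows in each context, with 9336, 5480 and 136 at an unadjusted p under 0.05, and edgeR called 0 in each, with 7340, 4327 and 96. These tests leave the difference between cell types in the residual. With cell type as a covariate the quasi-binomial test called 1 CG window, lower by -12.2 points at 40 °C, and 0 in CHG and CHH, with 17079, 12912 and 1932 at an unadjusted p under 0.05.

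Windows of 100 kb, chosen after the 2 kb windows had given almost no heat calls, showed the decrease region by region. In root hairs 724 of 9403 windows were called for CG and 370 of 7817 for CHG, each of them lower at 40 °C, with a median over all windows of -1.54 and -1.43 points. In stripped roots 1832 windows were called for CG, all lower, and 1259 for CHG, of which 1256 were lower. CHH gave 0 calls in either tissue by the quasi-binomial test, with 123 and 239 windows at an unadjusted p under 0.05; edgeR was not run on these windows. The CG level was lower at 40 °C in 92.4% of windows in root hairs and 94.7% in stripped roots. Since the windows share their 8 libraries, these calls are not independent of each other. In root hairs the CG count was 397 and 9 without root hair replicate 1 or 2 at 25 °C, 53 and 54 without root hair replicate 1 or 2 at 40 °C and 1236 without either stripped root library at 40 °C, and the CHG count was 1, 56, 0 and 721 without those 4 root hair libraries in that order. In stripped roots the CG count was 84 and 0 without stripped root replicate 1 or 2 at 25 °C and 2912 and 0 without stripped root replicate 1 or 2 at 40 °C, and the CHG count was 289 and 371 without those at 25 °C and 158 without replicate 2 at 40 °C. At matched depth the counts were 222 and 86 for CG and 623 and 85 for CHG.

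Whether heat acted differently in root hairs and stripped roots was tested as the interaction of cell type and temperature. The decrease in CG was -1.56 points in root hairs and -1.67 in stripped roots, and in CHG it was -1.43 and -1.58. A linear model of the 4 groups with 4 residual degrees of freedom, chosen after the values were seen, gave differences between these changes of 0.103 ± 0.467 points in CG, 0.151 ± 0.505 in CHG and 1.10 ± 2.85 in CHH (standard error; model p = 0.836, 0.780 and 0.718; exact permutation within cell types p = 1, 0.889 and 0.722). CHH sites per CG site changed by -0.235 in root hairs and -0.0685 in stripped roots, which is -12.8% and -6.13%. The difference of -0.166 ± 0.0376 had a model p of 0.0116, or 0.0578 after adjustment over 5 measures. The exact permutation p was 0.333 with temperatures exchanged within cell types. A decrease in both cell types raises that p, so it does not test the difference alone. The direction of the difference stayed at each read depth from 6 to 10, with -0.0479 at 6 reads and -0.250 at 10 reads. As a percentage it turned at 6 reads, with -8.57% in root hairs and -9.49% in stripped roots. The quasi-binomial test called 0 CG, 2 CHG and 0 CHH windows, with 10067, 7831 and 1674 at an unadjusted p under 0.05, and edgeR called 0, 1 and 0, with 9443, 7627 and 1583. In 100 kb windows the quasi-binomial test called 0 windows in each context, with 287, 320 and 95 at an unadjusted p under 0.05. The 2 CHG windows were on chromosome 7 from 16390001 to 16392000 and on chromosome 17 from 34326001 to 34328000, and both are named after their values were seen. On chromosome 7 the level was 66.1% ± 2.46 at 25 °C and 49.5% ± 1.05 at 40 °C in root hairs, and 46.9% ± 4.81 and 59.3% ± 1.26 in stripped roots (SD, n = 2 each; limma-moderated adjusted p = 0.0477, 22 sites). On chromosome 17 it was 93.9% ± 6.62 and 73.9% ± 1.61 in root hairs, and 79.0% ± 1.35 and 94.6% ± 1.49 in stripped roots (SD, n = 2 each; limma-moderated adjusted p = 0.00639, 8 sites). With any 1 library left out, 0 or 1 CHG window was called.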

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

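The tests of conversion and read depth for the CHH sites, of read depth for the temperature difference, the counts of other splits for 2 kb windows and site numbers, and the tests of how the change with temperature of site numbers per CG site differed between cell types were chosen after those results were seen; the tests of uneven coverage, of an equal factor, of CG windows lower in root hairs and of splits for the CHH share were written before theirs.

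Root hairs had more listed CHH sites per CG site than stripped roots. Read depth as the whole cause is argued against by the 5 read depths from 6 to 10, at each of which the cell types did not overlap, and uneven coverage of CHH-rich regions by the 86.3% of 2 kb windows in which the CHH share was higher in root hairs. Incomplete bisulfite conversion cannot be told apart from a difference between cell types. Windows with few CG and CHG sites held 0.524% of the excess, but unconverted cytosines would also list CG and CHG sites and so take windows out of this class, which makes that share no test, and no lambda reads are at hand. A difference between the cell types stays among the open explanations. Root hair libraries come from 1 kind of cell while stripped roots mix many, and no test here separates these possibilities.

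Levels were lower at 40 °C in CG and CHG in both cell types. Read depth is argued against, since at matched depth every 40 °C library lay below every 25 °C library of its cell type in 4 of 4 comparisons. A factor equal for all sites, such as loss of methylated cytosines in the bisulfite step, cannot be told apart from a change in the plants. The ratio of the 40 °C to the 25 °C level differed between windows of low, middle and high CG level by 0.00660, against a spread between replicates of 0.00526 in the low class, and by 0.00301 in CHG. The library preparation of each temperature is not described separately, so a difference in preparation could also be the source, and an effect of heat stays open as untested.

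CG windows called lower in root hairs at 25 °C went against the general direction. The 40 °C libraries took no part in the 25 °C difference, though they entered the spread and the choice of sites behind the call. In them 78.0% of the 259 windows were lower in root hairs, between the bounds set beforehand for chance and for a lasting difference. Chance in the 25 °C libraries thus cannot be told apart from a lasting difference for part of them. At matched depth 84.7% of the 137 windows that could be tested were lower, between the same bounds, and read depth stays open too. A mixture is possible in which some of these windows differ between cell types, a hypothesis not tested window by window.

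Chance as the source of the cell type calls is argued against in the pooled tests, at the smallest share that 35 splits allow, but is not excluded. Except for the CHH share, the splits were counted after the calls were seen. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many calls in each case. The counts were 27967 CG windows (highest other split 28), 38306 CHG windows (highest other 0), 25174 CHH windows (highest other 0) and 22163 windows by CHH share (highest other 0). By site number, tested on 15866 windows, they were 343 (highest other 1). For temperature the real count was 0 in CG, CHG, CHH, site number and CHH share. All 35 splits reach 0 by necessity, so nothing about chance follows there. The highest other split was the one by cell type, with the counts above. This split also separates the libraries by depth, with 3.75 to 5.32 reads per listed CG site in root hairs and 5.63 to 6.72 in stripped roots. The counts of splits thus cannot tell cell type from depth or preparation.

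A CHG window on chromosome 7 at 16390001 differed between cell types in its change with temperature by -28.9 points (tested, limma-moderated adjusted p = 0.0477). A CHG window on chromosome 17 at 34326001 did so by -35.6 points (limma-moderated adjusted p = 0.00639). CHH sites per CG site at matched depth decreased more in root hairs than in stripped roots in multi-context windows, by -0.243 against -0.0772, a difference of -0.166 (linear model adjusted p = 0.0111 over 14 measures; exact permutation within cell types p = 0.333). In the CHG-dense part the changes were -0.163 and -0.0364, a difference of -0.126 (linear model adjusted p = 0.0342 over 12 measures; exact permutation within cell types p = 0.333). The model assumes an equal spread in all groups of 2 libraries. The exchange within cell types assumes no change with temperature in either, so it does not test the difference alone. Over the genome the same difference did not pass after adjustment. CHG sites per CG site at matched depth changed by -0.0234 in root hairs and 0.00272 in stripped roots, with no overlap between the temperatures in either cell type. The difference was -0.0262 (linear model adjusted p = 0.128 over 5 measures, exact permutation within cell types p = 0.0556). CHH sites per CG site at matched depth were also compared in windows with few CG and CHG sites. Their group mean changed with temperature by -0.524 in root hairs and 0.511 in stripped roots. Here too the temperatures did not overlap in either cell type. The difference between these changes was -1.04 (linear model adjusted p = 0.368 over 14 measures, exact permutation within cell types p = 0.0556).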

How the results depend on the processing

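Matched depth, the 100 kb windows, the CHH share of windows and the classes of windows were chosen after the data had been seen; so were leaving out each library for site numbers per window, CCG, window classes, parts of the chromosomes and sites per CG site, and all alternatives of the change with temperature of single values; the rest were fixed before. Over 96 results and 1001 alternatives, 798 kept their direction and their side of the threshold or stayed within 1.5 times the count, 136 counts moved further, 13 values lost and 14 gained the threshold, and 40 changed direction, 32 of these on leaving out 1 library. Cell type differences in level and in CHH sites per CG site kept their direction in each alternative run, and the direction of called windows between cell types stayed with root hairs except for site numbers. For the moved values below the cause was not tested unless stated. Gene lists, gene bodies, upstream regions and their alternatives were not run, since the only gene table at hand did not match the build of the files. Depth limits the single windows: a minimum of 10 reads leaves 26827 CG, 17239 CHG and 7119 CHH sites of the 2868984, 2551284 and 559805, so fewer windows are tested and the counts fall by construction. For levels in 2 kb windows, every listed site, matched depth and leaving out a library also change which windows are tested. Counts of calls under these settings are thus not over the same windows as the main counts.

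With a minimum of 10 reads, calls for root hair against stripped root at 25 °C, at 40 °C and pooled were 149, 148 and 319 in CG, 96, 89 and 185 in CHG, and 147, 131 and 225 in CHH. Heat gave 0 calls in stripped roots in CG and in CHG and 1 in root hairs in CHG, and the CHG interaction gave 0. The CCG difference was 1.71 points and passed, and the heat difference in CG-only windows was -0.975 points and no longer passed. With every listed site, CG calls at 40 °C were 5157, CHG calls 26880, 23477 and 70037 and CHH calls 57185, 122615 and 161759; heat gave 1 CG and 1 CHG call in root hairs, 2 CG calls (both lower, against 1 higher before) and 4 CHG calls in stripped roots, and the interaction 6 CHG calls. With edgeR, CG calls were 2386 at 25 °C and 3651 at 40 °C, heat in stripped roots gave 0 CG and 1 CHG calls and the interaction 1 CHG call. With the other factor as a covariate, pooled heat gave 1 CG call.

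At matched depth, CG calls at 25 °C, at 40 °C and pooled were 1280, 652 and 13879, CHG calls at 25 °C and 40 °C 6859 and 4365, and pooled CHH calls 47180. Heat in stripped roots gave 3 CG calls, mostly lower, and 0 CHG calls, and the CHG interaction 0. In 100 kb windows heat in root hairs and in stripped roots gave 222 and 86 CG calls, 623 and 85 CHG calls and 1 CHH call in root hairs. Root hairs against stripped roots gave 8682 and 8615 CHH calls at 25 °C and 40 °C in 100 kb windows. Both exceed the 5066 windows of the main test, so more windows were tested at matched depth. Listed sites in root hairs minus stripped roots were -1.83 M (mega) in CG and -1.81 M in CHG at 8 to 15 reads, past the threshold there, and -1.80 M in CG, -1.80 M in CHG and -2.77 M in CHH with at least 10 reads, the last in the opposite direction. In CHH they also turned to -1.41 M at 8 to 15 reads, not past the threshold, and listed CHH sites at 40 °C minus 25 °C turned to 0.493 M with at least 10 reads. The edgeR test of CHH site numbers with at least 10 reads called 10399 windows, mostly lower in root hairs. Deeper libraries list more sites with at least 10 reads, and stripped roots were deeper. This bears on the plain numbers of listed sites. The edgeR test takes each library's total into account, so depth alone need not explain its calls.

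Replicate numbers are shared between groups, but nothing in the labels pairs them. With the replicate block the level differences of 3.23, 5.01 and 16.5 points had an exact sign-flip p of 0.125, the smallest that 4 differences allow, and the block took the call from 1 named window (CHH, chromosome 6 at 46066001), and moved no count of calls beyond 1.5 times. Single calls did change: the CHG interaction gave 3 calls, 1 of them higher, CHH calls lower in root hairs were 3 at 25 °C and 6 pooled, and CG calls at 25 °C were 5133.

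Leaving out each library in turn leaves a group with a single library, assumed to vary like the others. Calls between root hairs and stripped roots then ranged from 917 to 8767 in CG at 25 °C, 674 to 8730 in CG at 40 °C, 17224 to 33013 in CG pooled, 3103 to 16817 in CHG at 25 °C, 2980 to 15566 in CHG at 40 °C, 7725 to 23131 in CHH at 25 °C and 26646 to 38085 in CHH pooled; the lowest came without a library of that comparison, and the highest of the counts at 25 °C and pooled came without root hair replicate 2 at 40 °C, the shallowest library. By site number they ranged from 2309 to 3771 and by CHH share from 5051 to 19626. Heat gave 0 to 14 CG and 0 to 2 CHH calls in root hairs, 0 to 2 CG (2 calls without stripped root replicate 2 at 25 °C and 1 without stripped root replicate 2 at 40 °C, all lower) and 0 to 3 CHG calls in stripped roots, and the interaction 0 to 1 in CG and 0 to 1 in CHG. In 100 kb windows heat gave 9 to 1236 CG, 0 to 721 CHG and 0 to 3 CHH calls in root hairs and 0 to 2912 CG and 158 to 1481 CHG calls in stripped roots, and the interaction 0 to 4, 0 to 2 and 0 to 2. Cell type differences ranged from 1.74 to 2.54 points for CCG (past the threshold without root hair replicate 1 at 40 °C), 2.16 to 2.88 for CG and 1.77 to 2.47 for CHG in intermediate windows, -0.724 to -0.355 M listed CG sites and 1.29 to 3.11 M listed CHH sites. Heat differences ranged from -2.17 to -0.911 points for CG, -2.48 to -0.569 for CHG, -4.71 to 1.95 for CHH, -1.79 to -1.08 for CG in the CHG-sparse part, and -0.273 to -0.0315 for CHH sites per CG site. For CHH they ranged from -4.47 to 1.83 in multi-context windows and from -5.62 to 2.57, -4.45 to 1.62 and -4.00 to 1.80 in the CHG-sparse, middle and CHG-dense parts. Listed sites ranged from -0.0137 to 0.422 M in CG, 0.0662 to 0.506 M in CHG and -1.25 to 0.505 M in CHH. Leaving out a library unbalances the cell types, which differ more than the temperatures do.

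The difference between cell types in the change with temperature ranged, on leaving out 1 library, from -0.347 to 0.562 points in CG (past the threshold without stripped root replicate 1 at 40 °C), -0.298 to 0.592 in CHG and -1.46 to 3.94 in CHH, and at matched depth it was -0.530 in CG and -0.479 in CHG, the opposite direction. For CHH sites per CG site it was -0.0479, -0.0904 and -0.250 at 6, 7 and 10 reads, no longer past the unadjusted threshold, and it ranged from -0.202 to -0.130 without 1 library. It ranged from -0.0371 to -0.0152 for CHG sites per CG site (past the threshold without root hair replicate 1 or 2 at 40 °C) and from -1.35 to -0.718 for CHH sites per CG site in windows with few CG and CHG sites (past it without stripped root replicate 1 at 25 °C). On the log2 scale each of the 5 differences in sites per CG site stayed on its side of the threshold.

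The 51 windows named for a comparison of 2 groups or for the interaction were refitted one by one, in 596 fits. The call and direction were kept in 463 fits, the call was lost in 131 and the direction changed in 2. Of these windows 12 kept their call in every fit that could be run. With every listed site 31 of 51 kept it, at matched depth 7 of the 35 that could be tested, with edgeR 46 of 51 and without 1 library 329 of 408. The 2 changes of direction were CHH windows lower in root hairs at 40 °C that became higher with every listed site, on chromosome 9 at 8682001 (4.87 points) and chromosome 14 at 6550001 (9.61 points), neither called there.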

Other observations

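All tests of the values below were chosen after the data had been seen.

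The methylated-read threshold of the deposited calls differed between libraries. A CHH site needed 3 methylated reads from 26 and 21 reads on in root hairs at 25 °C, from 16 and 18 in stripped roots at 25 °C, from 31 and 22 in root hairs at 40 °C and from 21 and 19 in stripped roots at 40 °C. Between 6 and 10 reads the threshold was 2 in each library.

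CHH methylation in CG-only windows was sparse in both cell types. At matched depth these windows had 0.143 CHH sites per CG site in root hairs and 0.0977 in stripped roots (n = 4 each; exact permutation p = 0.0286, adjusted 0.0571), against 1.85 and 1.16 in multi-context windows. The CHH level at the few sites listed in all libraries was 58.7% in root hairs and 37.0% in stripped roots in CG-only windows, and 52.8% and 37.5% in multi-context windows. CG and CHG windows called lower in root hairs coincided in 31 windows where 1.02 would be shared by independent lists (Fisher's exact p = 7.11e-36), and 139 windows were lower in CG and higher in CHH where 110 would be shared, which was not tested.

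The difference between strands of a CWG pair was 16.2 points in root hairs and 17.8 in stripped roots (n = 4 each, exact permutation p = 0.0286, adjusted 0.0571). The limit from counting error given for CG pairs applies here too.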
